A study of Homo sapiens with 6 samples.

How the data were processed

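H3K27ac, a histone mark found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 3 established human bladder cancer cell lines, J82, 5637 and T24. Per the labels, each line has 1 ChIP library and 1 library of input DNA, 6 samples in all. The labels' protocol says that DNA from replicates was pooled before library preparation, which started from 20 to 30 ng. Each line is therefore 1 library, and no spread between replicates can be had. The lines are compared below as 3 libraries. No p-value between lines is given, and 95% intervals cover counting error only unless another source of spread is named. Input libraries were not analysed here on their own.

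The authors' files are lists of peaks, 1 list per line, each deposited as a text table and as a BED file. All rows of both forms were equal in position and score in each line. Per the submitters' processing notes, Bowtie 0.12.7, SAMtools and MACS were used with build hg19. The order of these steps, the version of MACS and its settings are not given in the sources used here. The deposited table gives, for each peak, a count of tags (reads counted in the peak, not scaled to depth). It also gives the ratio called fold enrichment over the local background (per the file headers), and an FDR in percent (per the file headers). The header of another column was overwritten, apparently by a spreadsheet program. Its values equal the deposited BED score, and its place in the table is that of the MACS score, 10 times the negative log10 of p. This score starts at 50, piles up at 3100, reaches at most 3233.06 in each list and is called the score here. Peaks with a score of at least 3100 were counted as at the cap. Length and summit position, deposited in bp, describe the peak itself. Tags, fold enrichment and score are the authors' own values for each peak. They were used to describe, rank or filter peaks within a list. The total number of reads per library is not in the tables used here, so depth is known only as the tags that fall inside peaks.

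Peaks on chromosome Y were left out, which leaves 23 chromosomes. Peaks of different lists were taken as overlapping from 1 bp on. The merged union of all lists gave the regions, each assigned to the lines with a peak in it. Similarity in bases was the Jaccard index, shared bases over bases covered by either list. Its interval came from resampling the 23 chromosomes (1000 draws). Bases with a peak in all 3 lines were counted apart from the merged regions, which are wider. That count and the sharing among peaks of 2 to 3 kb were added after the data had been seen. Chance overlap was described with 100 circular shifts of one list along each chromosome. Shares have exact Clopper-Pearson 95% intervals. Runs of missing regions were counted along each chromosome among the regions called in both other lines. The longest run after 1000 permutations of the missing regions is given beside them. Peaks closer than 12.5 kb were stitched into clusters and ranked by summed tags within a line. The implied background of a peak was its tags per bp divided by its fold enrichment. It is a proxy for the local level of reads. Tags cover the whole peak, and whether the fold enrichment does, or was taken at the summit or against the input, is not given in the sources used here. The value therefore also depends on the shape of a peak. Its median was taken over 2 Mb windows with at least 10 peaks, chromosome X left out, as a ratio to the median of the same list.

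Genes could not be placed on the peaks. The files use hg19, and the gene table used here is of GRCh38.p14, so no gene position was taken from it. It served for the number of protein-coding genes per chromosome, which was divided by the end of the last hg19 peak of that chromosome, and for the order of genes around CCNE1. The rule for named genes, the gene lists, the split into promoter and distal peaks, the CCNE1 locus by gene position and the motif counts, all fixed before the data were examined, were not computed for this reason. In their place the text names regions by position. For each line these are the line-only peaks with most tags, the 1 Mb windows with most line-only covered length, the 5 top clusters and the 3 longest runs of missing regions. Stitching used all peaks and not distal peaks alone. A window from 28 to 33 Mb of chromosome 19 was set to span band 19q12, named in the series title. Its limits come from general knowledge of the hg19 map. These replacements, the implied background and the counts by chromosome were chosen after the peak lists had been seen.

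The alternatives tried were a score of at least 100, an FDR of at most 1%, the 27222 strongest peaks of each list, an overlap of 50% of both peaks or of the shorter peak, stitching at 5 kb and ranking by covered length. Ranking by tags over implied background and background windows of 1 Mb were added after the data had been seen. Scripts ran under Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data made from the J82 list of 50396 peaks, with known overlaps, a known loss and a known gain. The interval code was also checked against a count base by base of the real J82 and 5637 peaks of chromosome 21. All 6 checks came within 2% of the known value.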

Results

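The series profiled H3K27ac in J82, 5637 and T24, cell lines derived from human urinary bladder carcinomas, with 1 library per line. Its title names an enhancer in band 19q12 and the expression of CCNE1, which encodes cyclin E1, a regulator of entry into DNA replication. The J82 list held 50396 peaks over 180.7 Mb, the 5637 list 50462 peaks over 161.6 Mb and the T24 list 27222 peaks over 105.7 Mb. Tags inside peaks summed to 17051226 in J82, 17295221 in 5637 and 15958162 in T24. The median peak held 167 tags in J82, 185 in 5637 and 301 in T24, counts that are not scaled to depth. Median peak length was 2745 bp in J82, 2544 bp in 5637 and 2970 bp in T24. The score was at its cap in 32.6% of T24 peaks (32.04 to 33.2), in 13.3% of J82 peaks (13.01 to 13.6) and in 12.8% of 5637 peaks (12.49 to 13.1).

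The first question was how far the acetylated regions of the 3 lines coincide. The merged lists gave 74310 regions. All 3 lines had a peak in 16815 of them, 22.6% of the regions (22.3 to 22.9). These merged regions made up 36.4% of the covered length, and the bases with a peak in all 3 lines made up 18.2%. J82 and 5637, without T24, shared another 9585 regions. T24 shared 2551 regions with 5637 alone and 1747 with J82 alone. Regions of a single line were the most frequent kind in J82, with 20269, and in 5637, with 18605, while T24 had 4738. The low T24 number went with its shorter list: with the 27222 strongest peaks of each list, 8703 J82, 7861 5637 and 8416 T24 peaks were called in that line only. Peaks called in all 3 lines had a median length of 3203 bp in J82, 2983 bp in 5637 and 3520 bp in T24, against 2287, 2115 and 1826.5 bp for peaks of that line only.

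**Figure D1:**
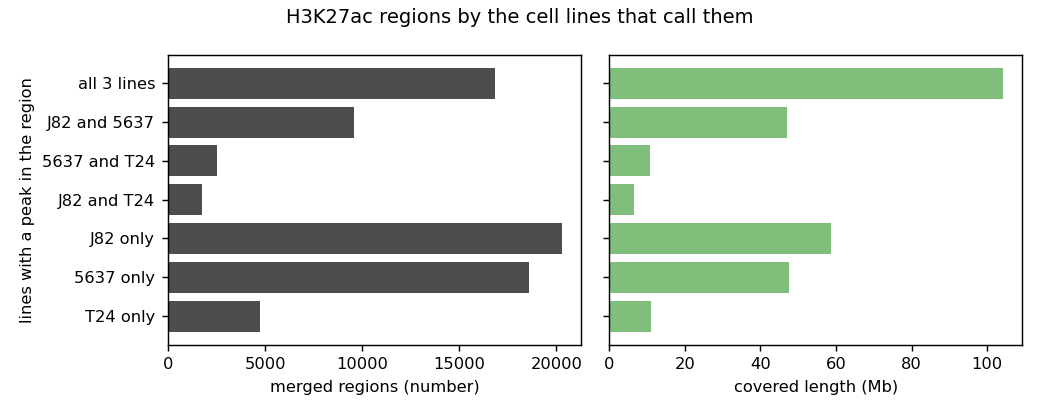
Horizontal bars give the number of merged H3K27ac regions (left) and their covered length in Mb (right) for each combination of cell lines with a peak in the region. Regions of all 3 lines number 16815 and cover 104.1 Mb, more than any other combination covers, while J82-only regions are the most numerous at 20269.

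Of the T24 peaks, 74.9% (74.3 to 75.4) met a 5637 peak and 72.0% (71.5 to 72.5) met a J82 peak. Of the J82 peaks, 55.6% met a 5637 peak and 39.4% a T24 peak. Of the 5637 peaks, 57.1% met a J82 peak and 41.9% a T24 peak. Shifted lists met on average between 6.19% and 11.8% of peaks, so each of these shares was well above chance placement. When each list was limited to its 27222 strongest peaks, the shares of all 6 pairings lay between 56.1% and 60.4%. The Jaccard index was 0.33 for J82 and 5637 (0.31 to 0.34 over resampled chromosomes), 0.32 for 5637 and T24 (0.30 to 0.34) and 0.29 for J82 and T24 (0.27 to 0.31). The index of J82 and T24 was 0.035 below that of J82 and 5637 (0.025 to 0.043), and its difference from that of 5637 and T24 was -0.030 (-0.037 to -0.021). The difference between J82 with 5637 and 5637 with T24, 0.0049 (-0.0039 to 0.013), was within the spread between chromosomes. With lists of equal length the index was 0.317 for J82 and 5637, 0.336 for 5637 and T24 and 0.309 for J82 and T24, so the order of the pairs depends on list length.

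Strong peaks were shared more often than weak ones. Among the 1000 peaks with most tags, 93.3% of T24 peaks (91.6 to 94.8), 69.4% of 5637 peaks (66.4 to 72.2) and 66.7% of J82 peaks (63.7 to 69.6) were called in all 3 lines. Among the 1000 with fewest tags these shares were 20.0% in T24, 7.4% in 5637 and 7.5% in J82. Long peaks meet others more easily, and the J82 peaks with most tags had a median length of 15699 bp against 919.5 bp for those with fewest. Among peaks of 2 to 3 kb alone, the share in regions of all 3 lines went from 13.6% in the weakest of 5 groups by tags to 91.1% in the strongest in J82, from 13.7% to 87.6% in 5637 and from 29.6% to 97.9% in T24. Peaks of all 3 lines held 88.2% of the tags inside T24 peaks, 55.2% in 5637 and 54.6% in J82. Of all peaks, 64.3% in T24, 35.8% in 5637 and 35.2% in J82 were called in all 3 lines. With the 27222 strongest peaks of each list, these peaks numbered 12987 in T24, 13080 in 5637 and 12914 in J82. That contrast therefore went with list length. The other shares above were not computed with lists of equal length, so no difference between lines is read from them. The regions that T24 lacked were not only sites that are weak in J82 or in 5637. The J82 peaks that 5637 also called were split by their tags into 5 groups of equal size. In the weakest group 61.4% had no T24 peak, and in the strongest group 24.8% (23.7 to 26.0) had none. Ranked by tags in 5637, these shares were 63.8% and 23.0% (21.9 to 24.1). In the full lists, 5637 lacked 3.73% (3.16 to 4.37) of the strongest group of J82 peaks that T24 called, and J82 lacked 6.81% (6.07 to 7.62) of the strongest group of 5637 peaks that T24 called. These are other sets of peaks, chosen by a call in the shorter T24 list and looked up in longer lists. The contrast with T24 is therefore partly built in, and it was not computed with lists of equal length.

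**Figure D2:**
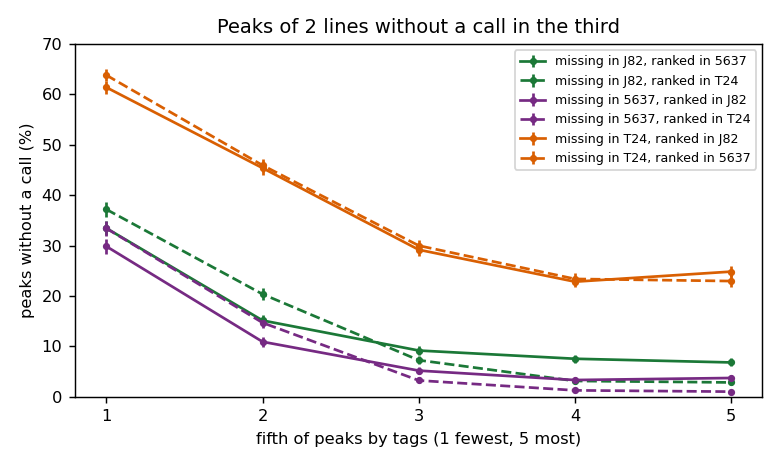
The percentage of peaks called in 2 lines that had no peak in the remaining line (vertical axis) is plotted for 5 groups of those peaks by their tags (horizontal axis, 1 fewest and 5 most); colours mark the line without a call, solid and dashed lines the list used for ranking, and bars the exact 95% intervals. Peaks without a T24 call fall from 61.4% to 24.8% when ranked in J82 and stay above both other lines in each group. The T24 list is the shortest, which builds in part of this difference.

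Peaks of the 3 lines were spread differently over the chromosomes. Chromosome 19 carried 6.01% of T24 peaks (5.73 to 6.30), against 3.17% in J82 (3.02 to 3.32) and 3.05% in 5637 (2.90 to 3.21). It was the chromosome on which T24 had about as many peaks as J82, 1636 against 1596. On chromosome 4, T24 had 949 peaks and J82 2660. T24-only regions showed the same lean, with 9.71% of them on chromosome 19 (8.88 to 10.6) and 2.55% on chromosome 4 (2.12 to 3.04). J82-only regions had 1.57% on chromosome 19 and 6.50% on chromosome 4. Regions called in all 3 lines had 5.60% on chromosome 19 (5.25 to 5.95) and 3.67% on chromosome 4 (3.39 to 3.96). Such regions make up a larger part of the T24 list, so part of the contrast may follow from its shorter length. The shares by chromosome were not computed with lists of equal length. Across the 23 chromosomes the ratio of T24 to J82 peaks was higher where protein-coding genes per Mb were more numerous, with a Pearson r of 0.84 and a Spearman rho of 0.81. Without chromosomes 17 and 19, which lay farthest from the median gene density, r was 0.76 and rho 0.76. The ratio of T24 to 5637 peaks gave r of 0.92 and rho of 0.85, and the ratio of 5637 to J82 peaks gave r of -0.079 and rho of 0.0020. These are the 3 ratios computed. With lists of equal length, rho was 0.73 for the ratio of T24 to J82 peaks and 0.83 for that of T24 to 5637 peaks. Chromosomes are parts of the same libraries and not replicates, so no p-value is attached.

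The second question concerned band 19q12. In the window from 28 to 33 Mb of chromosome 19 the lists held 17 peaks in J82, 16 in 5637 and 40 in T24, in 44 regions. With an FDR of at most 1% these were 12, 11 and 25 peaks. Between 30.0 and 30.6 Mb there were 13 regions, of which 6 had peaks in all 3 lines. The widest was called in J82 as 1 peak of 13976 bp from 30151370 to 30165345, with 2261 tags, more than 98.7% of J82 peaks. Within it 5637 had a peak of 6.29 kb with 900 tags, above 92.6% of its list, and T24 a peak of 4.96 kb with 569 tags, above 66.0% of its list. Neither reached the J82 summit at 30163418, where 5637 had a weak peak of 67 tags, from 30161780 to 30163720, and T24 had none. The region from 30176168 to 30182668 was a peak of 6.50 kb with a fold enrichment of 34.1 in J82. In 5637 and T24 it held only short peaks of 1.12 and 1.49 kb, with fold enrichments of 7.76 and 7.82, which did not overlap each other. A region from 30300729 to 30304678 was called in all 3 lines, with fold enrichments of 31.9 in J82, 21.2 in 5637 and 46.1 in T24. These exceeded 91.4%, 79.1% and 90.4% of the peaks of the respective lists.

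Other regions of this part of 19q12 separated the lines. A region from 30334553 to 30337604 had a peak in J82, with a fold enrichment of 27.9, and in T24, with 10.2, and none in 5637. A region from 30363839 to 30365116 was likewise called in J82 and T24, with 43 and 81 tags. A region from 30320783 to 30323428 had a peak in 5637, with a fold enrichment of 11.2, and a weak one in T24, with 5.39, and none in J82. The absence of a call is not the absence of signal, since reads outside peaks are not in the tables. In the gene order of GRCh38.p14, CCNE1 is preceded by VSTM2B, POP4, PLEKHF1 and C19orf12 and followed by URI1, ZNF536 and TSHZ3. No hg19 gene position was used here, so no peak of the window is assigned to one of these genes.

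In the distal part of the window, T24 had a dense stretch of its own. From 31493716 to 31777602 it had 22 peaks that covered 110.0 kb, 38.8% of the stretch. J82 had no peak over 2.40 Mb around it, from 30434963 to 32833867, and 5637 none over 2.31 Mb, from 30522480 to 32835654. The largest T24 peaks of the stretch were 18.3 kb long with 3807 tags, 17.9 kb with 2982 tags and 14.5 kb with 2673 tags, above 98.8%, 98.0% and 97.6% of T24 peaks. Of 24 T24-only regions between 31 and 32 Mb, 14 were left with a score of at least 100 and 11 with an FDR of at most 1%. The limits of the stretch were set around T24-only regions after they had been seen, which partly fixes its density. The implied background of its 2 Mb window was 1.22 times the median in T24 and 0.95 in J82, and 5637 had too few peaks there for a value. The J82 value comes from 10 peaks that all end by 30434963, outside the stretch. These values therefore do not compare the lines at the stretch itself.

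**Figure D3:**
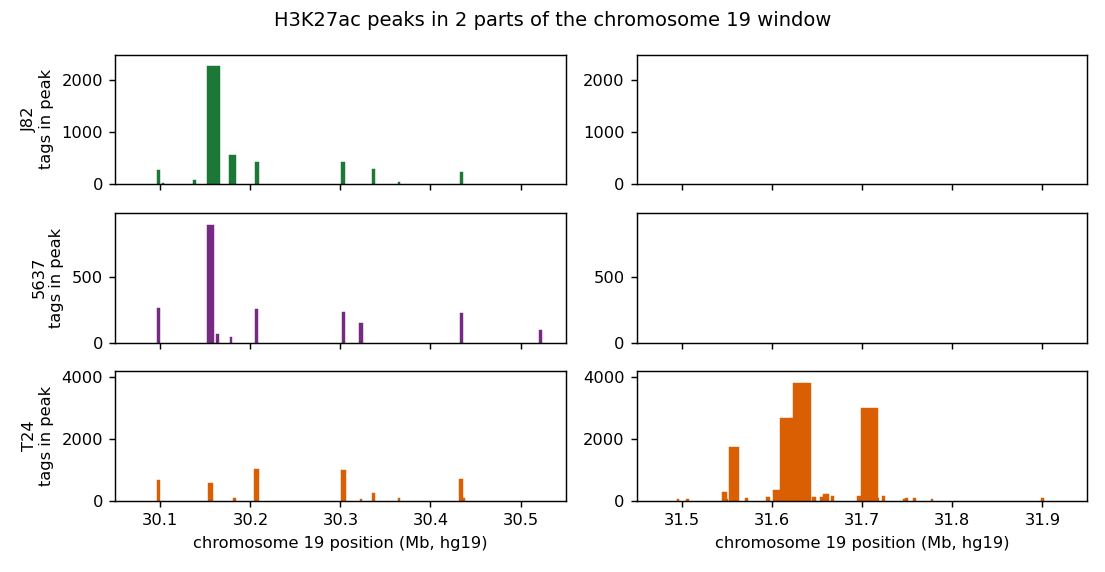
Bars mark H3K27ac peaks of J82, 5637 and T24 (rows) at their hg19 position in Mb on chromosome 19 (horizontal axis), with the number of tags in the peak as height (vertical axis, a separate linear scale per line). The left column shows regions common to the lines, including the 13976 bp J82 peak with 2261 tags, and the right column shows the stretch with 22 T24 peaks and none in J82 or 5637.

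Acetylation called in a single line was also summed over windows of 1 Mb. In T24 the 3 windows with most line-only covered length were 21 to 22 Mb of chromosome 19 with 202.6 kb in 47 regions, 37 to 38 Mb of chromosome 19 with 167.3 kb in 33 regions, and 7 to 8 Mb of chromosome 1 with 121.8 kb in 34 regions. The implied background of T24 in the last of these was 1.31 times its median. The window from 31 to 32 Mb of chromosome 19, with 114.0 kb, ranked among its top 5. In 5637 they were 41 to 42 Mb of chromosome 7 with 179.7 kb, 128 to 129 Mb of chromosome 8 with 158.7 kb and 29 to 30 Mb of chromosome 8 with 154.7 kb. The window at 128 Mb had an implied background of 1.52 times the 5637 median. In J82 they were 175 to 176 Mb of chromosome 4 with 152.9 kb, 34 to 35 Mb of chromosome 13 with 126.0 kb and 41 to 42 Mb of chromosome 4 with 123.1 kb. In the chromosome 4 window at 175 Mb, peaks covered 179.8 kb in J82, 9.82 kb in 5637 and 5.50 kb in T24.

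The strongest line-only peak of 5637 lay on chromosome 7 from 41134354 to 41164026, with 8089 tags over 29673 bp, in a window whose implied background was 1.33 times the 5637 median. That of T24 lay on chromosome 7 from 63510020 to 63546983, with 8002 tags. The next 3 of T24 were all on chromosome 19, at 37353803 to 37389330 with 6838 tags, 36929347 to 36946976 with 4444 tags and 57028502 to 57054603 with 4361 tags. That of J82 lay on chromosome 5 from 34785101 to 34822308, with 6862 tags, in a window whose implied background was 1.83 times the J82 median. The second J82 peak, on chromosome 5 from 24722654 to 24744372, had 5986 tags in a window at 1.61 times the median. The second of 5637, on chromosome 11 from 131919506 to 131951434, had 6309 tags.

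Stitching neighbouring peaks gave 30056 clusters in J82, 29796 in 5637 and 17098 in T24. The 500 clusters with most tags held 19.7% of the tags in J82, 18.7% in 5637 and 26.0% in T24, with median spans of 57.9, 55.8 and 55.3 kb. Of these 500, only 76 J82, 77 5637 and 79 T24 clusters overlapped a top-500 cluster of both other lines. Those that overlapped none numbered 299 in J82 (59.8%), 283 in 5637 (56.6%) and 281 in T24 (56.2%). Most of these were not bare in the other lines. Top-500 clusters without a single peak of either other line numbered 18 in J82, 18 in 5637 and 2 in T24.

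The first J82 cluster spanned 603.4 kb of chromosome 19, from 43234278 to 43837664, in 46 peaks with 79771 tags, and ranked 639 in 5637 and 1524 in T24. The second lay on chromosome 3 from 124750776 to 124889005, with 45384 tags. The next J82 clusters were on chromosome 20 from 49232332 to 49412793 and on chromosome 8 from 118837346 to 119157097 and from 59711777 to 59809523, the last of which had no T24 peak. The clusters of chromosomes 3 and 20 lay in windows where the implied background of J82 was 1.84 and 1.96 times its median, and those of chromosome 8 in windows at 1.29 and 1.43. The T24 list was led by a 204.7 kb cluster of chromosome 9, from 114653945 to 114858611, which ranked 64 in J82 and 144 in 5637. It was followed by clusters on chromosome 1 from 17412017 to 17619352, on chromosome 10 from 79102194 to 79404754, on chromosome 8 from 128805479 to 129013366 and on chromosome 19 from 1154401 to 1286858. The 5637 list was led by clusters on chromosome 3 from 13831691 to 13940214 and from 11166885 to 11294632. The next lay on chromosome 7 from 41123562 to 41304891, on chromosome 3 from 10204571 to 10269236 and on chromosome 1 from 209514992 to 209610786. The 3 clusters of chromosome 3 lay where the implied background of 5637 was 2.32 to 2.38 times its median. The order also depends on the stitching and ranking. At a stitching distance of 5 kb the largest piece of the first J82 cluster, from 43314976 to 43448441, ranked 3, and by covered length chromosome 20 led in 5637, from 48829570 to 49136654, and chromosome 10 in T24.

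The third comparison asked where a line lacked long stretches that both other lines had. J82 lacked 13.2% (12.7 to 13.7) of the regions called in 5637 and T24, 5637 lacked 9.41% (8.995 to 9.84) of those called in J82 and T24, and T24 lacked 36.3% (35.7 to 36.9) of those called in J82 and 5637. The T24 list is the shortest, and these shares were not computed with lists of equal length. No difference between lines is therefore read from them. The longest run in 5637 was of 14 regions on chromosome 20, from 9091506 to 9392088, and no permutation gave a run above 7. J82 had 19 peaks there and T24 32, which covered 66.3 kb and 151.6 kb, while 5637 had none from 9050012 to 9936150. The next runs in 5637 were 8 regions of chromosome 6, from 28565007 to 28772089, between which lay 1 5637 peak outside these regions, and 7 regions of chromosome 6, from 20533588 to 21635971. In the latter, 5637 had no peak over 2393 kb. With only peaks of a score of at least 100, the run on chromosome 20 was of 9 regions.

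**Figure D4:**
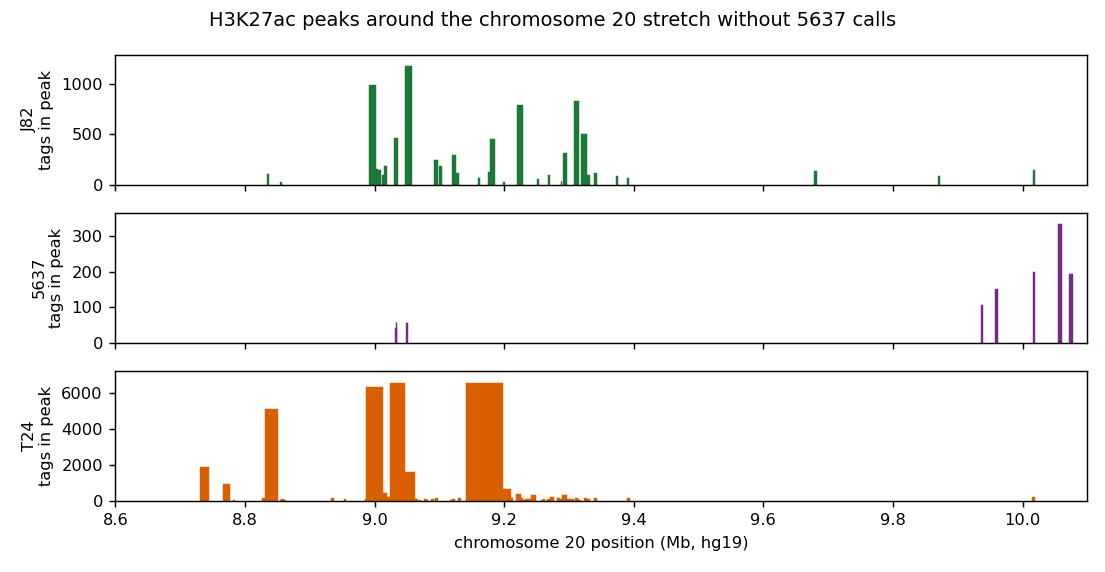
Bars mark H3K27ac peaks of J82, 5637 and T24 (rows) at their hg19 position in Mb on chromosome 20 (horizontal axis), with the number of tags in the peak as height (vertical axis, a separate linear scale per line). Between 9091506 and 9392088, J82 has 19 peaks and T24 32, and 5637 has none.

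In J82 the longest runs in the full lists were 10 regions of chromosome 14, from 73073146 to 73360923, and 9 regions each on chromosome 9 from 69768691 to 70387635 and from 119454310 to 119754092. No permutation gave J82 a run above 7. The longest J82 run lay on chromosome 9 under both alternatives, with 11 regions from 38967015 to 40738465 in lists of equal length and 9 from 69768691 to 70404396 with a score of at least 100. In T24 runs of 21 regions lay on chromosome 12 from 90123414 to 92476406, on chromosome 13 from 42907661 to 44425456 and on chromosome 3 from 177157216 to 178757521. The run on chromosome 13 held 2 T24 peaks outside its regions. The longest permuted run in T24 was 19. With the same number of peaks in each list the longest T24 run was 11, on chromosome 5, and with a score of at least 100 it was 18, on chromosome 7. Neither is among the 3 runs named for the full lists.

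The implied background, a proxy for the local level of reads, varied along each genome. The 5th and 95th percentiles of the windows were 0.84 and 1.34 times the median in J82, 0.83 and 1.299 in 5637 and 0.80 and 1.26 in T24. Windows at 1.5 or above numbered 25 of 1249 in J82, 7 of 1215 in 5637 and 3 of 879 in T24. In 5637 the highest lay from 8 to 14 Mb of chromosome 3, at 2.34 times the median (2.07 to 2.56, bootstrap over peaks), where J82 was at 0.91 and T24 at 0.99. A segment of chromosome 8 from 128 to 132 Mb was at 1.51 in 5637 (1.42 to 1.57), where J82 was at 1.27 (1.20 to 1.34) and T24 at 1.12. In J82 the segments of more than 1 window were 22 to 44 Mb of chromosome 5 at 1.70 (1.64 to 1.79), 120 to 128 Mb of chromosome 3 at 1.77 (1.71 to 1.96), and 30 to 34 Mb and 46 to 52 Mb of chromosome 20 at 1.77 (1.60 to 1.92) and 1.92 (1.83 to 2.01). T24 had no segment of more than 1 window, but it also had the fewest windows with enough peaks for a value, 879. Smaller shifts ran over long stretches. In J82 the median window was at 1.26 on chromosome 8 from 30 Mb on, against 0.88 before it, and at 1.27 on chromosome 3 from 140 Mb on, against 0.96 before it. The J82 windows of chromosome 3 before 140 Mb include the raised segment from 120 to 128 Mb, so these medians do not mark a single step. On chromosome 10 from 42 Mb on the median window was at 0.88 in J82, against 1.00 before it, and T24 was at 0.97 from 42 Mb on. The 5637 list was low on both sides, with a median of 0.87 from 42 Mb on and windows of 0.80 to 0.997 before, so no shift is read there. In 5637 it was 1.29 on chromosome 17 from 24 Mb on, where J82 was at 0.97 and T24 at 0.95. These stretches were picked from the windows after they had been seen.

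**Figure D5:**
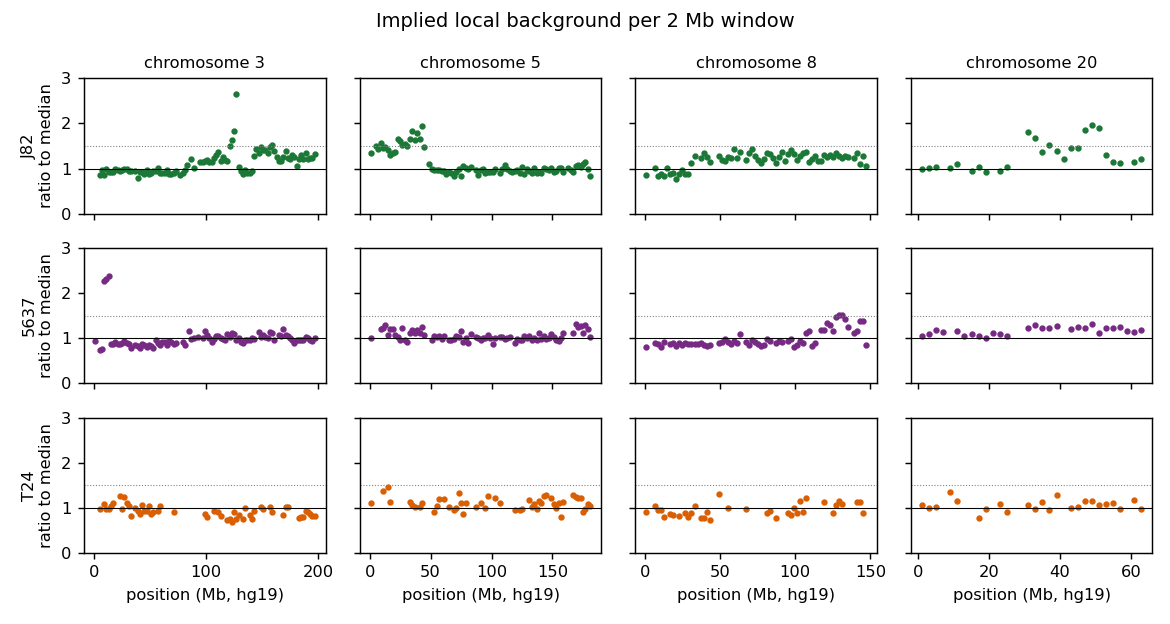
Points give the implied local background of J82, 5637 and T24 (rows) in 2 Mb windows along chromosomes 3, 5, 8 and 20 (columns; horizontal axis, hg19 position in Mb) as a ratio to the median of the same line (vertical axis); solid and dotted lines mark 1 and 1.5. The 5637 windows from 8 to 14 Mb of chromosome 3 stand at 2.34 as a group and J82 is raised on chromosomes 3, 5 and 20. No T24 window with enough peaks for a value reaches 1.5 on these chromosomes.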

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

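Tests chosen after the data had been seen were those of the chromosome 19 window, the line-only windows, the chromosome ratios and the implied background, and the cluster ranking divided by it. Of 81 values of the main results under an alternative, 66 stayed within 1.5 times the main count or, for the Jaccard index, within its interval. The 15 others were counts under shorter lists or a stricter overlap. Of 58 further values 30 moved, most of them shares of peaks that meet a peak of another line. J82 peaks that meet a 5637 peak were 55.6% and, with an overlap of 50% of both peaks, 40.5%. An FDR of at most 1% left 26941 J82, 31339 5637 and 20023 T24 peaks, with 8499, 11025 and 3278 of them in that line only. The T24 list was then still the shortest and held the fewest line-only peaks, and it had 25 peaks in the chromosome 19 window. With 27222 peaks per list, line-only peaks numbered 8703 in J82, 7861 in 5637 and 8416 in T24, so the low number of T24-only peaks went with the length of its list. The longest run missing in T24 then fell to 11, and the 5637 peaks in the chromosome 19 window to 10. A score of at least 100 left 2998 T24-only peaks and a longest 5637 run of 9. An overlap of 50% of both peaks left 11713 5637 and 11661 T24 peaks in all 3 lines and raised T24-only peaks to 8709. T24-only regions in 31 to 32 Mb of chromosome 19 numbered 24 in the full lists, 14 with a score of at least 100 and 11 with an FDR of at most 1%. The promoter window, CCNE1 gene position, promoter and distal split, gene body and motif alternatives were not run, since no hg19 gene positions or sequence were used. No paired analysis was possible because each line has 1 library, and no replicate could be left out for the same reason. Depth limits every statement on a missing call, since the reads outside peaks are not in the tables.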

Other observations

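The tests on peaks of low and of high fold inside raised segments and on runs within groups of equal J82 tags were set before their results were seen. All other tests of this part were chosen after.

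The T24 list has fewer peaks than those of J82 and 5637. With an FDR of at most 1% the gap was smaller, at 20023 T24 peaks against 26941 in J82 and 31339 in 5637. For the full lists 3 technical explanations were weighed. Joining of neighbouring peaks is argued against by the covered bases, which in T24 were 0.585 times those of J82. Loss only of sites weak in J82 is argued against by the strongest of 5 groups of J82 peaks that 5637 shares, of which 24.8% had no T24 peak. A site strong in J82 may be weak in T24, whose reads outside peaks are not known. Loss of sites weak in T24 therefore stays open. A smaller number of T24 reads stays open. Called peaks of equal length (1 to 2 kb) and fold enrichment (5 to 7) held 1.09 times (1.05 to 1.11) as many tags in T24 as in 5637. Against J82 the ratio was 1.37 (1.33 to 1.40). The median implied background was 6.68 tags per kb in T24, 6.30 in 5637 and 5.24 in J82. These values lean against fewer T24 reads, but a shallow list calls only peaks with enough tags, which can lift them by an amount not measured here. A difference between the cell lines and the settings of the peak caller in each line also stay open and untested.

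Segments of raised implied background may reflect copy gains of the cell lines, an untested hypothesis that the input libraries, not analysed here, could test. A property of the genome shared by all libraries is argued against as the whole cause, since the highest ratio of another line in the 6 segments of more than 1 window was 1.27. A second line was near this value in the 5637 segment of chromosome 8 and in both J82 segments of chromosome 20, so a shared part stays open there. Longer or stronger peaks are argued against as the whole cause in 5 of the 6 segments, where the ratio against peaks of the same length and fold was at least 1.41, while in the 5637 segment of chromosome 8 it was 1.22 (1.15 to 1.26) and the explanations cannot be told apart. These ratios come from the peaks by which the segments were picked, which may lift them. Among peaks of low fold and among peaks of high fold the ratio was at least 1.42 in each of the 6 segments, but the segments were picked by the median of these same peaks, so this does not speak for a copy gain. Copy gain and wide acetylation that lifts the reads around peaks cannot be told apart here.

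Clusters with most tags were partly those of raised segments. In 5637, 29 of the top 500 clusters and 3 of the top 5 by tags lay in raised segments, and 20 and 1 by covered length. In J82 they were 42 and 2 by tags and 31 and 1 by covered length, and in T24 5 and 0 by either. Ranked by tags over implied background they were 14 and 0 in 5637, 25 and 1 in J82 and 4 and 0 in T24. Raised segments and these rankings by tags rest on the tags of the same peaks, so part of these differences is built in. The share of all clusters in these segments was not computed.

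The run of 14 regions of chromosome 20 without 5637 calls was weighed next. Chance placement of single missing regions is argued against, since 0 of 1000 permutations gave a run of 14 or more and the longest was 7. The sites lean weak. Median tags of all peaks in the span were at percentile 38.4 of the list in J82 and 28.2 in T24, with at most 826 and 6555 tags. Of the 14 regions, 7 were in the weakest of 5 groups by J82 tags and 7 in that by T24 tags. Regions in the groups of the run lacked a 5637 call in 21.2% of cases on average, against 9.41% of all regions. Weakness is argued against as the whole cause, since permuting within 5 groups of J82 tags, or within 25 groups of J82 and T24 tags together, gave runs of at most 7. Loss of the segment from the 5637 genome requires that no 5637 peak lies inside, and 0 did. A segment that is present and not acetylated would give the same, so these cannot be told apart from peak lists without the input, which was not used here.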
